A study of Drosophila melanogaster with 4 samples.

How the data were processed

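Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments bound by a protein or carrying a histone mark, and sequencing shows where in the genome they lie. Here the mark was dimethylation of lysine 9 on histone H3 (H3K9me2), pulled down with an antibody that the labels number 2, from S2-DRSC cells. S2-DRSC is a cultured Drosophila melanogaster line derived from late embryos and labelled male. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and the DNA was purified after immunoprecipitation. The 4 samples form 2 groups, with 2 H3K9me2 ChIP samples and 2 inputs (sheared chromatin without immunoprecipitation). Each ChIP sample has 1 list of enriched clusters, and 1 further list covers the whole series and is called the combined list here. Per the labels, each input served as the input for 1 of the ChIP lists, and the inputs enter only through those calls. Nothing in the labels says whether the 2 ChIP samples came from separate cultures, so the spread between them may be technical.

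The deposited files list enriched clusters by sequence, start, end and a score. Per the file headers, positions are on FlyBase release 5. Per the submitters' processing notes, Bowtie 0.12.7 was used. The cluster caller, its threshold and the read filters are not given in the sources used here, and neither is the way in which the combined list was made. The score is the authors' own deposited value for each cluster, on a scale that the files do not define. Scores were therefore used only to describe and filter clusters within a list, and to compare rank orders. The lists give no read counts, so the depth of each sample is unknown and no interval based on counts can be given. The shortest cluster was 1001 bp in each of the 3 lists. Many clusters lie close together. Joining those within 1 kb of each other lowered the count from 4685 to 3735 in replicate 1 and from 5703 to 4582 in replicate 2. A cluster count thus depends on how the authors' caller joined neighbours.

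Coordinates are 1-based, as deposited. In each list, 3 clusters passed an end of their sequence, by at most 883 bp, and were trimmed to it. Sequence lengths came from the file headers, which name 14 sequences. They are the arms 2L, 2R, 3L, 3R and X, chromosome 4, 6 scaffolds of placed heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and 2 collections of unplaced sequence (U and Uextra). Heterochromatin is the compact, repeat-rich part of the genome around the centromeres. The proximal part of an arm was defined as the 1 Mb at its centromere end, which is at high coordinates on 2L, 3L and X and at low coordinates on 2R and 3R. The rest of each arm is called its interior. A cluster was assigned to one of these classes by its midpoint, and covered shares were counted per base.

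Covered length, covered share and overlap were computed with Python 3.11.15 and NumPy 2.4.6. Agreement of positions between replicates was tested on the 12 placed sequences in bins of 100 bp. The replicate 2 map was moved by a random circular shift within each sequence 100000 times. The one-sided p is the share of shifts with at least the observed shared length, with the observed map counted among the shifts. The position of coverage was tested for each replicate by rotating its map a random distance along the joined placed sequences 100000 times, as a two-sided permutation test. Scaffolds of chromosomes 2, 3 and X were set next to their own arms in this order, and YHet came last. Both tests keep the lengths and local spacing of clusters. They compare positions within these lists and say nothing about other cultures. Values exist for 1 group of samples only, so no test across samples was run. The 8 rotation tests (4 region classes in 2 replicates) were adjusted together by the Benjamini-Hochberg method. The interval of the shared share came from resampling 1 Mb blocks 2000 times. For each sequence, the shared share was set beside that of 2 independent maps with the same coverage. Rank correlations used SciPy 1.17.1.

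The tests were checked on simulated maps with 3806 clusters of the lengths in the replicate 1 list, placed independently of each other. Unrelated maps gave p under 0.05 in 4% of 100 simulations of the shift test. Where 50% of clusters were copied from one map to the other, 20 of 20 simulations (100%) gave p under 0.05. For the rotation test of X against the autosomes, 2.5% of 40 maps without an excess on X gave p under 0.05. With a cluster density on X of 1.7 times that elsewhere, the mean recovered ratio of covered shares was 1.60, because clusters overlap, and 100% of those maps passed. Real clusters lie in groups, which these maps do not imitate, so the rates need not hold for the real maps.

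Regions were named by a rule written before the data were examined: the 10 longest clusters of the combined list and its 10 longest clusters in arm interiors. The alternatives listed at the same time were a score minimum at each list's median, a length minimum of 1 kb, joining of clusters within 1 kb of each other, other sizes of the proximal part, shifts within arm interiors, cluster-wise overlap, and each replicate alone. Further alternatives were added later and are named with their results. A comparison of gene lists was planned for the case that an annotation of the same release was at hand. The gene table used for this work is on release 6, so genes were not analysed here and regions are given by position only.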

Results

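H3K9me2 was profiled by ChIP-seq in 2 samples of the male Drosophila line S2-DRSC, and each sample was set by the authors against its own input to call enriched clusters. H3K9me2 is a histone mark of heterochromatin, which is concentrated around the centromeres and on the small chromosome 4. The replicate 1 list held 4685 clusters that covered 26.2 Mb, or 15.5% of the release 5 sequence. In the replicate 2 list, 5703 clusters covered 32.2 Mb, or 19.1%. The mean was 5194 ± 720 clusters and 29.2 ± 4.26 Mb (SD, n = 2). Most clusters were short, with a median length of 2699 bp in replicate 1 and 2572 bp in replicate 2, while the longest reached 263 kb and 268 kb. The read depth behind the calls is unknown. The data address 2 questions, namely whether both samples mark the same places and where on the chromosomes those places are.

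The 2 samples marked largely the same bases. Of the bases in replicate 1 clusters, 95.02% also lay in replicate 2 clusters, and 77.3% of the bases in replicate 2 clusters lay in replicate 1 clusters. In all, 24.9 Mb was covered in both samples, 1.30 Mb in replicate 1 alone and 7.33 Mb in replicate 2 alone. The shared part was 74.3% of all bases covered in either sample (95% interval over 1 Mb blocks, 70.7 to 77.2%). On the placed sequences the samples shared 22.4 Mb, 3.01-fold more than the 7.41 ± 0.513 Mb (mean ± SD over shifts) expected for maps shifted at random within each sequence (permutation test, one-sided p = 1e-05, the smallest that 100000 shifts can give). Within arm interiors alone the excess was 5.11-fold (permutation test, one-sided p = 1e-05, also the smallest possible).

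The share of covered bases common to both samples differed between sequences, as did the share that coverage alone would give. The bases covered in both were 90.6% of those covered in either on 3RHet, 90.0% on 2LHet and 2RHet, 88.4% on chromosome 4, 87.5% on 3LHet and 87.1% on XHet. On YHet, with 1 and 2 clusters, the share was 62.5%. The corresponding shares were between 63.8% on 3R and 74.9% on 2R for the long arms, with 68.4% on X. For maps of the same coverage placed independently, the share would be 65.3% on chromosome 4 and between 36.6% on 2RHet and 45.6% on 3RHet for the Het scaffolds of chromosomes 2 and 3 and X. It would be between 4.37% on 3R and 13.6% on X for the long arms. The difference in agreement between sequences was not tested. Clusters seen in one sample only were short, though a longer cluster also has more room to meet the other map. In autosome interiors, 1049 of 2604 replicate 2 clusters met no replicate 1 cluster, and these had a median length of 1599 bp against 4317 bp for those that did. In the X interior 413 of 1038 replicate 2 clusters met none, with median lengths of 1630 bp and 4556 bp. On the unplaced sequence the 2 medians were closer, at 1850 bp and 2163.5 bp. In the other direction, 8.08% of replicate 1 clusters in the X interior and 7.72% in autosome interiors met no replicate 2 cluster.

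**Figure D1:**
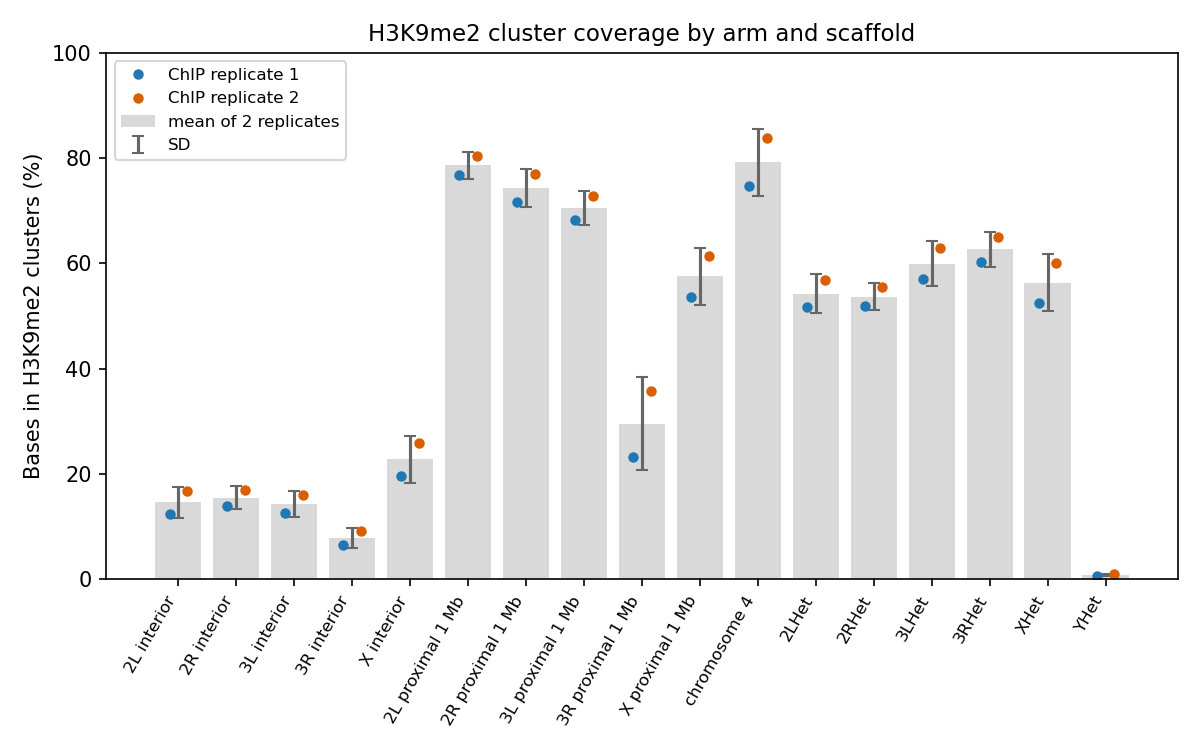
Share of bases in H3K9me2 clusters (percent) for each arm interior, the 1 Mb at the centromere end of each arm, chromosome 4 and the Het scaffolds. Grey bars are means of 2 replicates with SD, and points are the 2 ChIP samples; chromosome 4 is at 74.7% and 83.8%, the 3R proximal part at 23.3% and 35.8%, and YHet below 1% in both.

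H3K9me2 clusters covered most of the 1 Mb at the centromere end of every long arm except 3R, and little of the arm interiors. The proximal 1 Mb of the 5 long arms was covered at 62.1 ± 4.77% (SD, n = 2), against 14.6 ± 2.75% of the interiors. The proximal share was 4.64 times the interior share in replicate 1 and 3.96 times in replicate 2, and the difference between the classes was far larger than the spread between samples. The proximal share itself, 58.7% in replicate 1 and 65.5% in replicate 2, lay above its mean over rotations of 18.02% and 22.1% (two-sided permutation test, Benjamini-Hochberg adjusted p = 0.0142 in both). The arms were not alike. Proximal coverage was 78.6 ± 2.57% on 2L, 74.4 ± 3.66% on 2R, 70.5 ± 3.28% on 3L and 57.5 ± 5.47% on X, while on 3R it was 29.6 ± 8.88%. On 3R the first 250 kb from the centromere end was covered at 38.5% and 53.6%, and the next 250 kb at 32.9% and 57.4%, for replicates 1 and 2. Coverage did not fall evenly from there, with 10.5% and 13.3% from 750 to 1000 kb and 45.2% and 46.5% from 1250 to 1500 kb. On 2L the stretch from 750 to 1000 kb was covered at 90.8% and 93.6%, and on 2R at 87.7% and 90.6%.

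Dense coverage reached beyond the first megabase on some arms. On 2R the window from 1 to 2 Mb was covered at 67.2% in replicate 1 and 72.0% in replicate 2. On 3L the window from 22 to 23 Mb stood at 62.0% and 65.0%, and on 2L the window from 21 to 22 Mb at 60.8% and 67.3%. On X the 1 Mb windows between 18 and 21 Mb ranged from 31.2 to 41.3% in replicate 1 and from 38.9 to 49.8% in replicate 2.

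**Figure D2:**
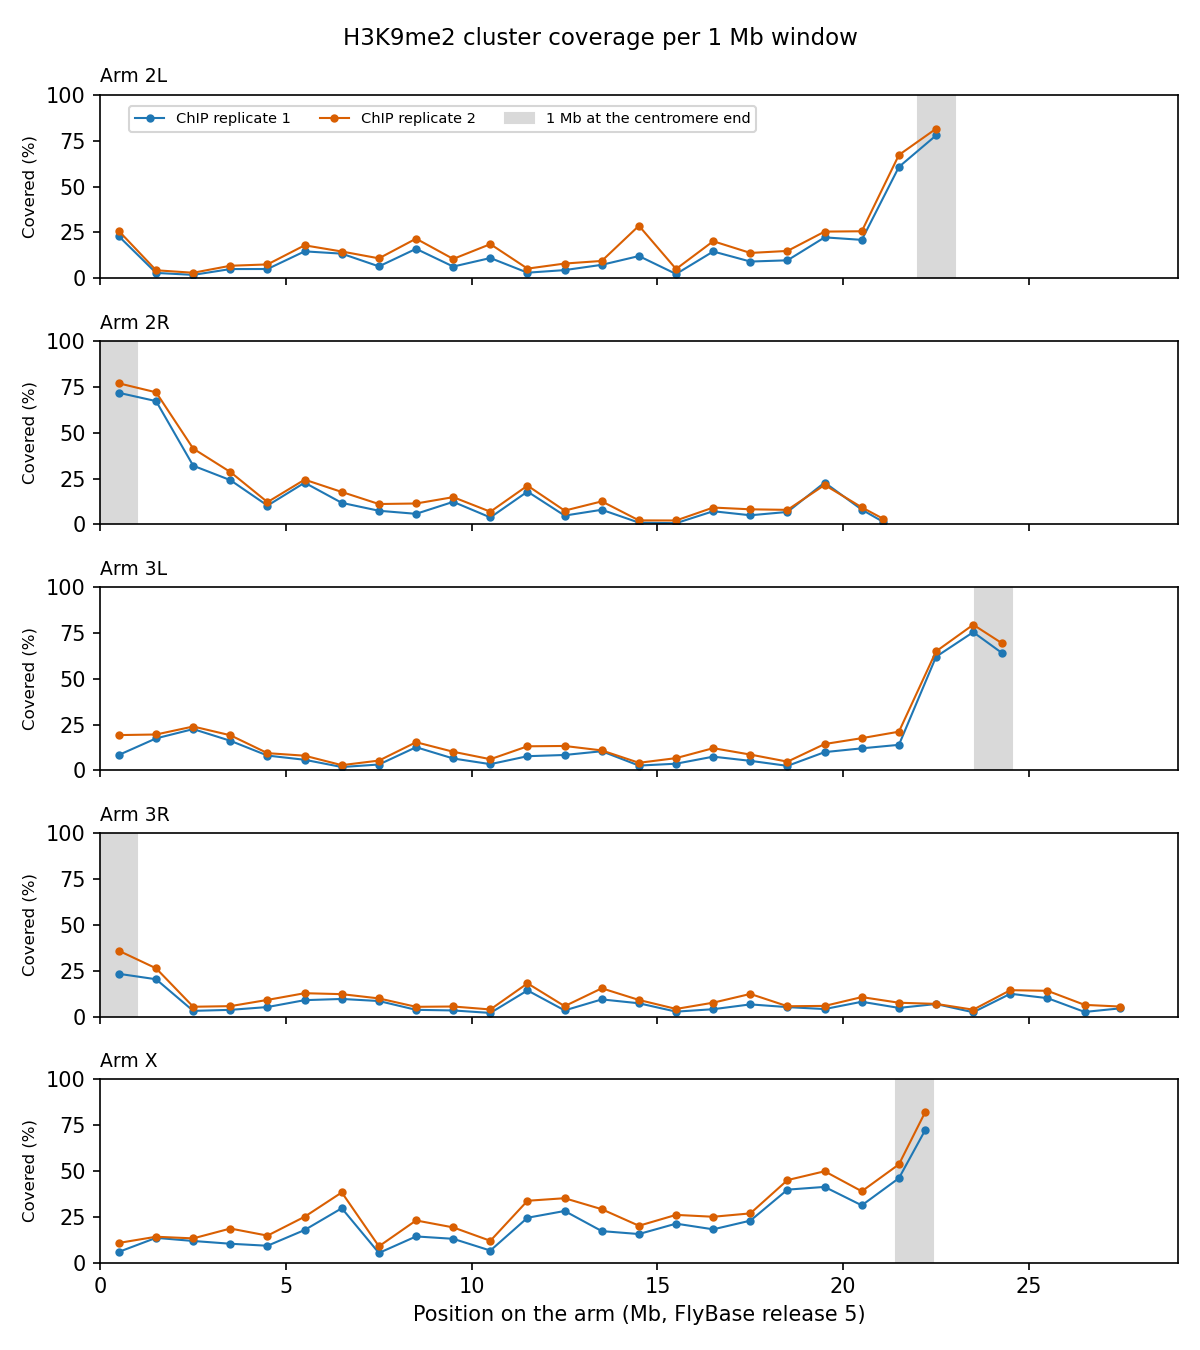
Share of bases in H3K9me2 clusters (percent) in 1 Mb windows along the 5 long arms, against position in Mb on release 5, for ChIP replicates 1 and 2; the grey band is the 1 Mb at the centromere end, and end windows under 100 kb are not drawn. Coverage is highest at or near the centromere end of every arm, and on X the windows from 18 Mb on are above 30% in both replicates.

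Chromosome 4, the small chromosome known to carry heterochromatin interspersed with genes, was the most densely covered sequence. Clusters held 74.7% of its 1.35 Mb in replicate 1 and 83.8% in replicate 2, a mean of 79.2 ± 6.39% (SD, n = 2) and 5.90 and 5.06 times the share of the arm interiors. The covered share lay above its mean over rotations, 18.02% in replicate 1 and 22.1% in replicate 2 (two-sided permutation test, adjusted p = 0.0234 and 0.0142). Coverage ran from position 53499 to 1277294 in replicate 1 and from 54307 to 1278245 in replicate 2. In the last 100 kb of the chromosome it was 18.4% and 25.02%. Replicate 1 divided this stretch into 97 clusters with a median length of 6902 bp, and replicate 2 into 48 with a median length of 15248 bp. The longest chromosome 4 cluster in the combined list, at 717588 to 808194 (90.6 kb), was covered at 99.6% in replicate 1 and completely in replicate 2. When each list was limited to clusters at or above its median score, chromosome 4 coverage was 51.7% in replicate 1 and no longer passed the test (two-sided permutation test, adjusted p = 0.125), against 82.6% in replicate 2.

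The scaffolds of placed heterochromatin were also covered over most of their length, with YHet as the exception. Over the 6 scaffolds the covered share was 53.6% in replicate 1 and 58.3% in replicate 2 (two-sided permutation test, adjusted p = 0.0424 in both). It was 62.7 ± 3.37% on 3RHet, 59.97 ± 4.25% on 3LHet, 56.3 ± 5.44% on XHet, 54.2 ± 3.67% on 2LHet and 53.7 ± 2.58% on 2RHet (SD, n = 2). YHet, the 347 kb of sequence from the Y chromosome, held 1 cluster in replicate 1 and 2 in replicate 2. They covered 0.578% and 0.925% of it.

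Outside the proximal parts, X was covered at 22.7 ± 4.43% (SD, n = 2), against 15.4 ± 2.21% for 2R, 14.6 ± 2.98% for 2L, 14.2 ± 2.44% for 3L and 7.86 ± 1.90% for 3R. The ratio of X to autosome interiors was 1.77 in replicate 1 and 1.80 in replicate 2. This excess, though nearly equal in both samples, did not pass the rotation test (two-sided permutation test, adjusted p = 0.389 and 0.310). Those rotations also carried dense proximal, Het and chromosome 4 coverage into the interiors, so their spread includes where that coverage landed. Rotation along arm interiors only was added after the data were seen. The excess did not pass there either (two-sided permutation test, p = 0.111 and 0.0984, 0.111 in both after adjustment over the 2 replicates). Clusters of at least 20 kb numbered 28 on the X interior in replicate 1 and 42 in replicate 2, or 13.1 and 19.6 per 10 Mb. The 2L interior had 11.8 and 15.4 per 10 Mb, 2R 10.4 and 12.4, 3L 8.07 and 10.2, and 3R 2.602 and 4.46. These counts were not tested.

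The score that the authors gave each cluster ranked these classes of regions in the same order in both lists. Within replicate 1 the median score was 2.40 on the Het scaffolds, 1.95 in proximal parts, 1.25 on chromosome 4, 1.07 in the X interior and 0.813 in autosome interiors. Within replicate 2 these medians were 3.19, 2.69, 2.58, 1.197 and 0.906. Scores are not on a stated scale and were not compared in size between lists. Across 3741 clusters of the combined list met by both samples, the highest scores in the 2 samples had a Spearman rank correlation of 0.874. This correlation is across regions, which are not independent replicates. It was 0.784 across the 2169 such clusters in arm interiors.

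The combined list held 5130 clusters over 30.1 Mb. Of its bases, 82.6% lay in both replicate lists, 11.6% in replicate 2 only, 3.51% in replicate 1 only and 2.30% in neither. It contained 99.9% of the bases shared by the replicates, 99.0% of all replicate 1 bases and 88.0% of all replicate 2 bases. Its longest clusters were covered almost fully in both samples. Among the 13 regions named by the fixed rule, no region was covered at less than 96.2% in either replicate. The regions were picked from a list that covers the same samples, so this is no separate evidence of agreement.

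The longest cluster, 268 kb, lay on 3L at 22281909 to 22549935, followed on the same arm by 93.7 kb at 22616713 to 22710393. The next longest on any arm, 171 kb, was on X at 17806141 to 17977163. Its 1 Mb window was covered at 22.9% in replicate 1 and 26.8% in replicate 2, most of it by this cluster itself. A 124 kb cluster on 2L at 21989804 to 22113654 and a 114 kb cluster on 2R at 1317902 to 1431717 lay near the centromere ends of their arms. On 2RHet, 108 kb was covered without a break in the combined list at 1871059 to 1979342. On 3L a 92.4 kb cluster at 1972184 to 2064558 lay near the telomere end of the arm, across the border of the window from 1 to 2 Mb (17.5% and 19.6%) and that from 2 to 3 Mb (22.6% and 24.0%). Further X clusters lay at 20180383 to 20262301 (81.9 kb) and at 11819777 to 11900074 (80.3 kb). The 10 longest interior clusters comprised 4 on 3L, 3 on 2R, 3 on X and none on 2L or 3R. Those on 2R (starting at 1317902, 1672644 and 2385791) lay in the dense coverage that reached beyond the first megabase. So did those on 3L starting at 22281909, 22616713 and 23196345. These clusters counted as interior because the border was fixed at 1 Mb. Genes within these regions were not analysed here.

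**Figure D3:**
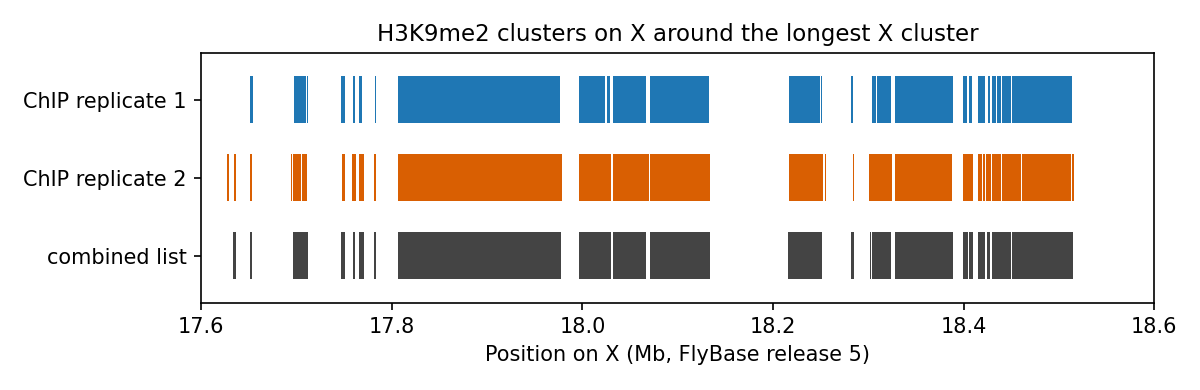
H3K9me2 clusters in the 1 Mb of X (position in Mb, release 5) that holds the longest X cluster, in ChIP replicate 1, ChIP replicate 2 and the combined list; each filled bar is a cluster drawn to scale along the position axis. The 171 kb cluster at 17806141 to 17977163 is a single bar in all 3 lists, with shorter clusters on both sides.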

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

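No test was run in this part. The unplaced sequence was left out of the shift and rotation tests, and drew attention because clusters were called on it. In the combined list they covered 21.5% of U and 4.74% of Uextra. U was covered at 18.4% in replicate 1 and 21.6% in replicate 2, and Uextra at 3.38% and 4.69%. Of the bases covered in either sample, 52.1% were covered in both on Uextra and 75.7% on U, against 2.00% and 11.1% for independent maps of the same coverage. Median scores of unplaced clusters were 2.73 in replicate 1 and 3.37 in replicate 2, above those of the Het scaffolds in the same lists.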

How the results depend on the processing

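Alternatives chosen after the data were seen were leaving out U and Uextra, YHet, 3R, the proximal 5 Mb or the 10 longest X clusters, the interior median score, rotation along interiors only, and scores in arm interiors. Of 50 recomputed values, 45 were counted as kept. A tested value had to keep its direction and its side of the threshold, the cluster number to stay within 1.5 times, and covered length and shared share to stay within the SD or the interval. The combined list composition and the score correlation have no such spread, and their alternatives were counted as changed. The X to autosome ratio was counted as kept where it stayed above 1 and still failed its test, which says little about stability. The 45 include all values for the length minimum of 1 kb, which removed no cluster, and for each replicate alone. Neither tests the stability of a call: 1 of 2 replicates always lies within 1 SD of their mean, and the larger p of the replicates was already the one used. With clusters at or above each list's median score, the mean covered length was 21.0 Mb and the mean cluster number 2598, since that choice leaves fewer clusters. Chromosome 4 coverage then was 67.1% with an adjusted p of 0.125, against 0.0234 with all clusters and 0.0223 with clusters within 1 kb joined. The loss came from replicate 1 (51.7%, against 82.6% in replicate 2). There the median score of chromosome 4 clusters, 1.25, lay under the cut of 1.37, so most of them were removed. In replicate 2 it was 2.58, above the cut of 1.42. Why chromosome 4 clusters ranked lower in replicate 1 was not tested. Counted per cluster, 65.6% of combined clusters had at least 50% of their length in both replicates, a different unit from bases. The rank correlation of scores was 0.784 in arm interiors, and the cause was not tested. The ratio of X to autosome interiors, as a mean of the 2 replicates, lay between 1.53 and 2.13. The larger adjusted p of the 2 replicates lay between 0.111 and 0.554 (two-sided permutation tests). The planned gene list comparison was not run. No paired analysis was possible because the inputs have no cluster lists of their own. Read depth is unknown, so bases outside clusters are not shown to lack the mark.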

Other observations

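The tests of explanations in this part were chosen after the patterns they address had been seen, and those of XHet and of the proximal 5 Mb after their own values were also known. In the distal 100 kb of the arms, away from the centromere, coverage was 16.5% and 29.5% on 2L, 8.78% and 45.1% on 3L, 3.71% and 13.4% on X, 2.06% and 4.52% on 2R and 1.01% and 4.01% on 3R, for replicates 1 and 2. The samples stood furthest apart on 3L.

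YHet was almost free of clusters (0.578% and 0.925% covered), unlike the other 5 Het scaffolds. Small size as the explanation is argued against by windows of the same length, started every 100 bp on the Het scaffolds of chromosomes 2 and 3. Of these 73427 windows 0% were covered as little, and the lowest was at 15.2%. The windows overlap heavily and are not independent, so their number is no sample size. A failure of calls on short scaffolds is argued against as well, because the still shorter XHet was covered at 52.5% in replicate 1 and 60.2% in replicate 2. A candidate explanation is that these cells carry little or no Y chromosome DNA, although the line is labelled male. Few uniquely mappable positions on YHet could give the same picture, and neither was tested, because reads and inputs were not used here.

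The X interior was covered 1.77 and 1.80 times as much as autosome interiors. In these 2 maps the excess was also present among clusters at or above the interior median score, at a ratio of at least 2.10. Low-scoring clusters alone thus did not carry it. X interior clusters had higher median scores than autosomal ones (1.07 against 0.813 in replicate 1, 1.197 against 0.906 in replicate 2). The score cut therefore favoured X and cannot tell whether weak calls added to the excess. Neither a few very long clusters nor the centromere end alone held the excess. The ratio was at least 1.497 without the 10 longest clusters on X and at least 1.91 without the proximal 5 Mb of every arm. Separately, the mean ratio was 1.54 without 3R, the least covered arm. A chance arrangement of grouped clusters stays open, because no setting passed the rotation test in both replicates. The larger adjusted p of the 2 replicates was from 0.111 to 0.554 over the alternatives (two-sided permutation tests). The lowest, for rotation along interiors only, was adjusted over the 2 replicates alone. A difference in copy number or depth between X and autosomes could also bear on the excess and was not tested, and no biological explanation was tested.

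The replicate 2 list was longer than the replicate 1 list, with 1997 clusters that met no replicate 1 cluster. If replicate 1 had missed only weak clusters, these should lie low in the score order of replicate 2. In arm interiors their median was at percentile 35.3, between the bounds of 25 and 50 set for and against, so this stays open there. With 40.1% of interior clusters unmatched, the lower bound asked for an almost complete separation of scores. Unmatched against matched medians were 0.776 against 1.12 in autosome interiors and 1.07 against 1.31 in the X interior. On the unplaced sequence the median was at percentile 73.8, above the upper bound. In replicate 1 too, unmatched unplaced clusters scored higher than matched ones (medians 3.30 and 2.68). Score thus may not rank weak calls there, and the test cannot decide. Elsewhere, the median score of unmatched against matched replicate 2 clusters was 1.48 against 2.73 in proximal parts (55 unmatched) and 0.972 against 2.65 on chromosome 4 (4 unmatched). On the Het scaffolds it was 3.14 against 3.19 (74 unmatched). In replicate 1 the order was reversed in proximal parts (2.89 against 1.94, 8 unmatched) and on the Het scaffolds (2.88 against 2.40, 10 unmatched). The 1 unmatched replicate 1 cluster on chromosome 4 also scored higher, while those in arm interiors scored lower. The lower replicate 2 values in proximal parts and on chromosome 4 go with missed weak clusters but do not decide the question. A difference in read depth may also account for part of the excess and was not tested, and neither was any biological explanation, since the labels name no difference between the samples.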
